A study of Homo sapiens with 8 samples.

How the data were processed

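Messenger RNA was measured in 8 sections of frozen human prostate transition zone with benign prostatic hyperplasia on Visium slides, where each spot is a small region that can hold several cells of different types. The deposited matrices hold UMI counts per gene and spot, which the authors made with Space Ranger 1.2.0 on GRCh38, per the submitters' processing notes, as filtered matrices of spots under tissue, with no normalization. The other deposited files hold spot barcodes and the names of 36601 features in the order of the matrices. The annotation release used for counting is not given in the sources used here, and spot positions and images were not used here. Of the features, 34587 matched GENCODE release 29 by Ensembl identifier and took their GRCh38 coordinates from it, and 132 Y-linked features and XIST were left out. Total depth per section ran from 10989227 to 30844949 UMIs.

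The number in the titles was taken to mark the specimen, which the labels do not state, and sections with the same number were summed, giving 6 specimens. Gene lists, class definitions, tests, the rule for named genes and most alternatives were fixed before the data were examined. Spots under 500 UMIs were left out, which removed 296 of 28883. Expression per spot was scaled to 10000 counts and log-transformed after adding 1. In each section, epithelium-rich and stroma-rich spots were the upper and lower 33.33% by the mean z-score of an epithelial minus a stromal marker list. Among epithelium-rich spots, club-high and luminal-high spots were the upper and lower 25% by a club minus a luminal score, and among stroma-rich spots muscle-high and fibroblast-high spots were set the same way. The classes are ranges of a score and not cell types. Spots within 0.1 of the threshold made up 6.3% and 7.29% of all spots for the epithelium-rich and stroma-rich classes, 4.83% and 9.27% of the epithelium-rich spots for the club-high and luminal-high classes, and 7.55% and 7.71% of the stroma-rich spots for the muscle-high and fibroblast-high classes.

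Counts were summed per specimen and class, giving 12 libraries per comparison. Both classes of a comparison come from the same sections, so the specimen was a block, with 5 residual degrees of freedom. edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05) was run in R 4.3.3. Genes that defined the classes counted toward library size and were left out of the tests, and each club and luminal gene was tested with classes rebuilt without it. Log2 fold changes are the first class named against the other, and CPM values are means over specimens. Gene lists of at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, and with fry, adjusted over the lists of a comparison.

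Named genes were the 10 with the largest increase and the 10 with the largest decrease among those past the threshold, changed the same way in all 6 specimens and with a mean of at least 20 CPM. Class-defining, immunoglobulin and T cell receptor segment, mitochondrially encoded, ribosomal protein and Y-linked genes and XIST were excepted. From each list described, the text names genes among the 4 with the lowest adjusted p. A few genes that this rule takes in are not reported here.

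For correlations across spots, each epithelium-rich spot was thinned to 2000 UMIs, and a partial Spearman rho with the epithelial minus stromal score held fixed was computed per section and averaged per specimen. A two-sided exact sign-flip permutation test over the 6 specimens used all 64 sign patterns, with adjustment over 39 lists. Spots were clustered with the Leiden method of igraph 0.11.9 (2000 variable genes, 30 components, 15 neighbours, resolution 0.5). Clusters were described by leading genes, leaving out HLA and immunoglobulin genes. No doublet caller was run.

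The edgeR step was tested on simulated counts. For epithelium-rich against stroma-rich spots (15677 genes) it recovered 72% of genes changed 1.5-fold and 100% of those changed 2-fold, with 14 false among 186 calls. For club-high against luminal-high spots (13477 genes) the values were 72% and 97%, with 17 false among 186. For muscle-high against fibroblast-high spots (11730 genes) they were 60.2% and 95.88%, with 15 false among 167. In each comparison the share of false calls was above the threshold set for the adjusted p. At most 100 genes were changed at each fold, against 793 to 8605 genes called in the data. The simulation covered the edgeR step and not the sorting of spots on an expression score. It therefore does not give the error rate of these comparisons.

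Alternatives covered DESeq2 1.42.0 and its size factors, no filter on low counts, no specimen block, sections as blocks, each specimen left out, other definitions of classes and axes, and, chosen after seeing the data, axes freed of leukocyte score or depth, the omission of specimens 4 and 5, and clustering centred within sections. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps.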

Results

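Spatial transcriptomes were measured in 8 sections of frozen human prostate transition zone with benign prostatic hyperplasia, on Visium slides that capture the messenger RNA of small tissue regions, called spots, each holding several cells. All 8 sections carry the same labels, so they form 1 group and no groups of sections were compared. The number in the titles was taken to mark the specimen, which gave 6 specimens, of which 2 had 2 sections each. The labels do not say what that number means. The edgeR p-values rest on how the class difference within a specimen varied across these specimens. Those of camera compare a list with the other genes. The sections held 2327 to 4510 spots under tissue and 10989227 to 30844949 UMIs (counted molecules), 182141371 in all. Median depth lay between 3952 and 6051 UMIs and between 1854 and 2805 genes per spot, and mitochondrial transcripts made up 2.17% to 5.66% of the UMIs. Of 28883 spots, 28587 with at least 500 UMIs were used. The series is about a club-like state of luminal epithelium at low androgen, and no label gives an androgen level or a treatment. Comparisons were therefore made between spot classes within each specimen.

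Epithelium-rich spots carried secretory and androgen-regulated transcripts, and stroma-rich spots carried contractile, matrix, vascular and leukocyte transcripts. Rankings of single genes are among called genes with a mean of at least 20 CPM that changed the same way in 6 of 6 specimens, outside the classes of genes excepted. By that rule the largest increases in the epithelium-rich spots were in ORM2, an acute-phase plasma protein, with a log2 fold change of 2.82 ± 0.34 (SE, n = 6), and MMP7, a matrix metalloproteinase of glandular epithelium, with 2.21 ± 0.15. Single specimens ran from 0.52 to 4.07 for ORM2, which had 2.30 without specimen 5 and only 2 and 0 UMIs in specimen 2, and from 1.63 to 2.71 for MMP7. MSMB, a major protein of prostatic secretion, averaged 17170 ± 13310 CPM (SD, n = 6) in epithelium-rich and 3420 ± 1265 CPM in stroma-rich spots. The largest decreases by the same rule were in HAPLN2, a link protein of hyaluronan, at -2.57 ± 0.13, and NEXN, an actin-binding protein, at -2.53 ± 0.11. ACTG2, the smooth muscle gamma actin, fell from 3812 ± 2366 to 719.9 ± 510.6 CPM.

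By the same rule, the other genes with the largest increases were MAL2, CWH43, MYBPC1, the kallikrein KLK11, the metallothionein MT1G, PRAC1 and the arginase ARG2, with log2 fold changes from 2.14 for MAL2 to 1.93 for ARG2. The others with the largest decreases were CNN1 (calponin), HSPB7, DES (desmin), ECRG4, WFDC1, JPH2 and SCRG1, from -2.41 for CNN1 to -2.32 for SCRG1. Each of these 20 genes changed the same way in 6 of 6 specimens. edgeR's quasi-likelihood test with the specimen as a block called 4310 genes higher and 4295 lower of 15774 tested at an adjusted p of 0.05, and 7229 of the 8605 called genes moved the same way in all 6 specimens. ORM2 had an adjusted p of 4.24e-05 and HAPLN2 of 5.27e-07 by edgeR.

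Of 27 androgen target genes tested, 26 were higher in epithelium-rich spots and 1 did not pass (median log2 fold change 1.43). They included PART1 (1.57), DHRS7 (1.60) and STEAP2 (1.22). All 6 luminal secretory genes rose, among them AZGP1 (1.78) and NEFH (1.84), and 5 of 6 club genes rose, among them LCN2 (1.63), which binds bacterial siderophores, and PIGR (1.496), the receptor that carries immunoglobulin across epithelium. Genes of zinc, citrate and polyamine metabolism were higher in 13 of 17 cases and lower in 1, with SMS (spermine synthase) at 1.41 and SLC30A4 (a zinc transporter) at 1.55. Genes of lipid and sterol synthesis were higher in 11 of 15 and lower in 1, with SCD (stearoyl-CoA desaturase) at 1.65 and SQLE (squalene epoxidase) at 1.21. The unfolded protein response had 9 of 13 higher and 1 lower, with XBP1 at 1.33 and HSPA5 at 0.77. Basal cell markers were higher in 10 of 14 and lower in 2, with LAMB3 at 1.58 and COL17A1 at 1.84 but DKK3 at -0.75. Adjusted over the list alone, the counts were 26 of 27 for androgen targets, 13 of 17 for zinc, citrate and polyamines, 12 of 15 for lipids, 9 of 13 for the unfolded protein response and 10 of 14 for basal markers. limma's camera placed each of these lists above the other genes, with adjusted p from 1.24e-09 for androgen targets to 0.01005 for the club genes. None of these calls held with an estimated correlation, where the adjusted p was 0.31 for androgen targets, the luminal and club genes, zinc and the unfolded protein response, and 0.328 for lipids and basal markers.

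In stroma-rich spots, 18 of 22 extracellular matrix genes were higher, so that COL4A1, a basement membrane collagen, was at -1.66 and COL6A3 at -1.77 in epithelium-rich spots. Of 26 growth factors and their regulators, 19 were lower in epithelium-rich spots and 3 higher, and FGF7, a stromal growth factor that acts on epithelium, stood at -1.84 beside BMP4 at -1.61 and RSPO3, an enhancer of Wnt signalling, at -2.71. Smooth muscle markers outside the axis were lower in 9 of 10 cases (MYOCD -2.20, PLN -2.15) and endothelial markers in 11 of 11 (ENG -1.27, ACKR1 -1.58). Leukocyte markers were lower too: 13 of 13 for T and NK cells (NKG7 -1.51), 11 of 12 for macrophages and dendritic cells (CSF1R -1.28) and 9 of 11 for B and plasma cells (CD79A -2.17). MHC class II genes were lower in 10 of 10 cases and interferon response genes in 11 of 20 with 2 higher (BST2 -1.54). The genes of androgen metabolism and steroid receptors parted, with 5 higher and 7 lower of 16. SRD5A2, the steroid 5-alpha reductase of the prostate, was lower in epithelium-rich spots by -1.58, as were HSD17B6 at -1.73 and PGR, the progesterone receptor, at -1.53. Adjusted over the list alone, 18 matrix genes, 21 growth factors, 9 smooth muscle, 11 endothelial, 13 T and NK cell, 12 macrophage, 9 B and plasma cell, 10 MHC class II and 12 interferon genes were lower. Apart from androgen metabolism (camera adjusted p 0.241), camera called each of these lists, with adjusted p from 3.72e-08 for the matrix to 0.000869 for the interferon response, and each had adjusted p = 0.31 with an estimated correlation. The classes differed in depth, with section medians of 5725 to 9659.5 UMIs per spot in epithelium-rich and 2612 to 4752 in stroma-rich spots, and the mitochondrial share was higher in epithelium-rich spots in 2 of 8 sections. Without the specimen block edgeR called 4975 genes. ORM2 has a near-identical neighbour, ORM1, and the share of its counts that belongs to each is uncertain.

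**Figure D1:**
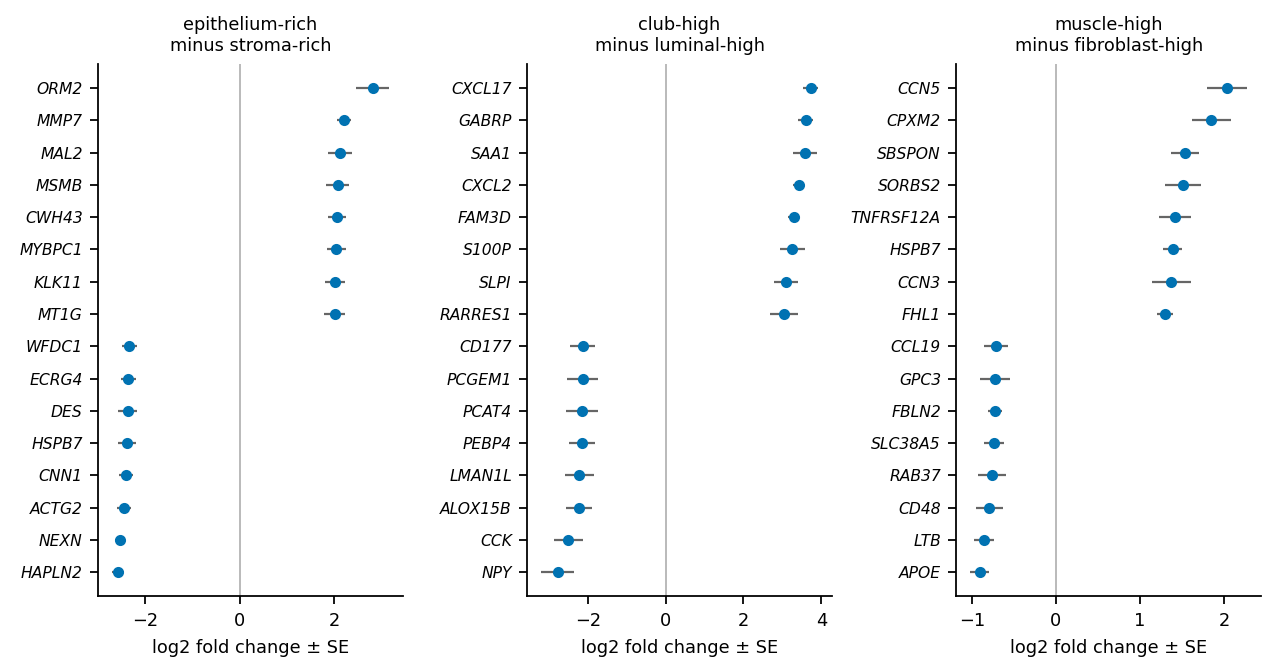
The 8 genes with the largest log2 fold changes each way among those that passed an adjusted p of 0.05 in edgeR, had a mean of at least 20 CPM, changed the same way in 6 of 6 specimens and lay outside the classes of genes excepted, for the 3 comparisons of spot classes. Points are fitted log2 fold changes and bars are standard errors, with CXCL17 at 3.72 and NPY at -2.78 at the ends of the panel for club-high against luminal-high spots.

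Club-high and luminal-high spots, which lie within the epithelium-rich class, differed in mucosal defence, inflammation, androgen target and lipid genes. In club-high spots CXCL17, a mucosal chemokine, was higher by a log2 fold change of 3.72 ± 0.19 (SE, n = 6), at 60.94 ± 59.67 against 4.62 ± 4.87 CPM (SD). GABRP, a GABA receptor subunit of secretory epithelia, was higher by 3.599 ± 0.20, and OLFM4, a glycoprotein of glandular progenitor cells, averaged 816.3 ± 964.2 against 46.72 ± 56.46 CPM (SD). All 26 androgen target genes tested were lower in club-high spots, with a median log2 fold change of -1.23. The score that sorted the spots subtracts luminal genes, among them the androgen-regulated KLK3 and KLK2. A fall of the androgen target, lipid, zinc and luminal lists may therefore follow in part from the sorting, which was not tested.

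The classes were the upper and lower 25% of epithelium-rich spots of each section by a club score minus a luminal score. Each scoring gene was tested only with classes built without it, and all 12 passed. The other scoring genes of both lists stayed in, so a gene can pass by varying with them. This is no independent test of the score. In club-high spots MMP7 was higher by 3.83 ± 0.35, PIGR by 3.63 ± 0.22, LTF (lactoferrin) by 3.54 ± 0.27, LCN2 by 3.09 ± 0.23, SCGB3A1 by 2.07 ± 0.40 and SCGB1A1, the secretoglobin that marks airway club cells, by 2.03 ± 0.49. PIGR and SCGB1A1 were higher in 5 of 6 specimens and the others in 6 of 6. In epithelium-rich spots LTF stood at only 0.48 CPM in specimen 5, and PIGR and LCN2 at 0.55 and 1.56 CPM in specimen 4. Their directions in those specimens rest on few UMIs. KLK3, which encodes prostate-specific antigen, was lower by -2.43 ± 0.42, and MSMB, NEFH, ACPP (prostatic acid phosphatase), KLK2 and AZGP1 were lower by -2.43, -2.46, -2.28, -2.03 and -1.09. Their edgeR adjusted p lay between 4.25e-06 for PIGR and 0.00829 for SCGB1A1.

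edgeR called 2300 genes higher and 2330 lower in club-high spots of 13611 tested, and 3365 of the 4630 moved the same way in all 6 specimens. Among genes with a mean of at least 20 CPM that changed the same way in 6 of 6 specimens, the largest increases after CXCL17 and GABRP were in SAA1 (3.58), an acute-phase protein, CXCL2 (3.42), a neutrophil chemoattractant, FAM3D (3.29), S100P (3.26), SLPI (3.10), a mucosal protease inhibitor, RARRES1 (3.04), CHI3L2 (3.04) and GPRC5A (3.02). The largest decreases among such genes were in NPY, a neuropeptide, at -2.78 ± 0.42, and in CCK (-2.50), ALOX15B (-2.21), a lipoxygenase, LMAN1L (-2.21), PEBP4 (-2.14), the long noncoding RNAs PCAT4 (-2.14) and PCGEM1 (-2.13), CD177 (-2.13), AOC1 (-2.09) and RLN1, a relaxin (-2.08). Each of these moved the same way in 6 of 6 specimens, but specimen 4 held at most 3 UMIs per class of CXCL17, GABRP, CXCL2, S100P and GPRC5A, too few to give a direction there. CXCL17 had an edgeR adjusted p of 1.32e-06 and NPY of 0.000817.

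The androgen targets with the lowest adjusted p were DHRS7 at -1.86, C1orf116 at -0.89, HOMER2 at -0.76 and SPDEF, a transcription factor of luminal cells, at -1.42, and 26 of 26 were lower adjusted over the list alone. limma's camera gave the list an adjusted p of 2.78e-14, and the call was lost at adjusted p = 0.318 with an estimated correlation. fry, which tests whether the genes move one way on balance, gave an adjusted p of 0.0103. These tests take the sorted classes as given, so they do not separate the fall of the list from the sorting. Of 15 genes of androgen metabolism and steroid receptors, 3 were lower, among them the transcription factors HOXB13 (-0.89) and FOXA1 (-0.52), 4 were higher, among them AKR1C3 (1.002), and 8 did not pass, with the same counts adjusted over the list alone. Its camera adjusted p was 0.84.

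All 17 NF-kB and inflammation genes rose in club-high spots, with a median of 1.52, among them the chemokines CXCL1 (3.63), CCL20 (3.91) and CXCL8 (2.66). Of 18 antimicrobial and mucosal genes 16 were higher and 1 lower, among them the mucin MUC4 (2.82), the elastase inhibitor PI3 (3.76), CP (3.77), which encodes ceruloplasmin, and BPIFB1 (3.76). Specimen 4 held 0 UMIs of CCL20, MUC4, PI3 and OLFM4 in both classes and at most 3 per class of CXCL1, CP and BPIFB1. The club score that sorted the spots holds LCN2, LTF and PIGR, themselves genes of mucosal defence. A rise of the NF-kB and antimicrobial lists may therefore follow in part from the sorting, which was not tested. Interferon response genes were higher in 14 of 20 cases and lower in 1, with CXCL9 at 3.36 and GBP2 at 1.33. MHC class II genes rose in 10 of 10 cases (CD74 1.43, HLA-DPB1 0.99) and MHC class I genes in 9 of 12 (PSMB9 0.996, TAP1 0.68). Leukocyte markers rose in the same spots: 13 of 13 for T and NK cells (CD3E 1.44), 10 of 11 for macrophages and dendritic cells (C1QC 1.60), 5 of 10 for B and plasma cells (JCHAIN 1.82) and 3 of 3 for neutrophils (CSF3R 0.82). Adjusted over the list alone the counts were 17 NF-kB, 16 antimicrobial, 15 interferon, 10 MHC class II, 10 MHC class I, 13 T and NK cell, 11 macrophage, 6 B and plasma cell and 3 neutrophil genes higher. camera called all 9 lists, with adjusted p from 2.43e-10 for NF-kB to 0.0341 for neutrophils. With an estimated correlation the adjusted p was 0.318 for NF-kB, antimicrobial, interferon, MHC class II, T and NK cell and macrophage genes and 0.345 for MHC class I, B and plasma cell and neutrophil genes.

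All 15 genes of lipid and sterol synthesis were lower in club-high spots (median -1.04), among them INSIG1 (-1.29) and FADS2 (-1.27), a fatty acid desaturase. Of 13 unfolded protein response genes 10 were lower (HERPUD1 -0.90, HSPA5 -0.63) and of 17 zinc, citrate and polyamine genes 10 were lower (ACLY -1.02, MT1G -1.07, SLC39A6 -0.94). Luminal markers outside the axis were lower in 10 of 13 cases and higher in 2 (ANPEP -2.04 but GDF15 1.90). Basal cell markers were higher in 8 of 14 cases (KRT23 1.82, S100A2 2.34), markers of hillock cells, a squamous-type epithelium, in 5 of 8 (KRT4 3.23, KRT13 2.40), and a list of progenitor-type luminal genes in 7 of 12 with 3 lower (OLFM4 4.22, PROM1 2.89). Proliferation genes were higher in 8 of 10 (TOP2A 1.60, MCM5 0.62), immediate early genes in 8 of 13 (JUNB 1.10), apoptosis regulators in 6 of 12 (BCL2 0.88, an inhibitor of apoptosis, but also BBC3 1.23, which promotes it), extracellular matrix genes in 15 of 22 (TNC 0.68) and growth factors in 9 of 22 with 3 lower (IGFBP3 1.69). Markers of stromal cells moved with the matrix and growth factor genes, with fibroblast markers outside the axis higher in 6 of 10 cases and smooth muscle markers outside the axis in 3 of 11, or 6 and 4 adjusted over the list alone. Their camera adjusted p was 0.0246 and 0.0168, and 0.412 and 0.345 with an estimated correlation. In specimen 6 the median log2 fold change was -0.28 for fibroblast, -0.54 for smooth muscle, -0.12 for matrix and -0.27 for growth factor genes. That of the hillock genes was -0.40 and -0.30 in specimens 4 and 5, with at most 3 UMIs of KRT4 per class in both and of KRT13 in specimen 5. fry called neither the hillock genes (adjusted p 0.109) nor the fibroblast markers (0.0867). Adjusted over the list alone, 15 lipid, 12 unfolded protein, 11 zinc and 10 luminal genes were lower, and 8 basal, 5 hillock, 7 progenitor-type, 9 proliferation, 10 immediate early, 6 apoptosis, 16 matrix and 9 growth factor genes were higher. camera called the lists named in these counts except the progenitor-type genes (adjusted p 0.0587). With an estimated correlation the adjusted p was 0.318 for lipid, unfolded protein, zinc, luminal, basal and proliferation genes, 0.345 for progenitor-type, immediate early, apoptosis, matrix and growth factor genes and 0.412 for hillock genes.

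**Figure D2:**
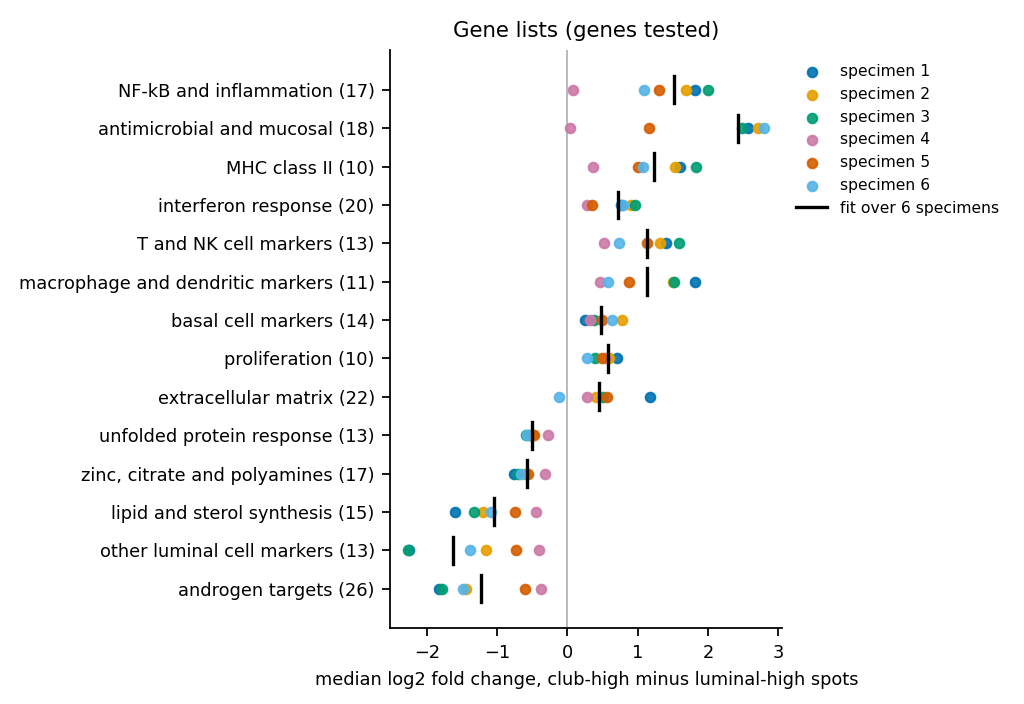
Median log2 fold change of 14 gene lists between club-high and luminal-high spots, with 1 point per specimen, a black line for the fit over 6 specimens and the number of genes tested in brackets. The androgen targets lie below 0 in each specimen, with a fitted median of -1.23, and the NF-kB list has a fitted median of 1.52.

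Section medians were 4988 to 9576.5 UMIs per spot in club-high and 9304 to 12867 in luminal-high spots, and the mitochondrial share was higher in club-high spots in 5 of 8 sections. Summed over the 6 club genes, epithelium-rich spots held 2386, 2266, 4177, 50, 111.2 and 5597 CPM in specimens 1 to 6, and the club-high spots of specimens 4 and 5 held 133 and 323.8 CPM against 7502 to 14749 CPM in the others. Luminal-high spots held 11.43 and 26.6 CPM in specimens 4 and 5 and 342.1 to 966.5 CPM in the others. The club-high spots of specimens 4 and 5 thus lay below the luminal-high spots of the others. In specimen 4 stroma-rich spots held 56.32 CPM, above its epithelium-rich spots. Club-high is a rank within a section, and in these 2 specimens it marks spots with few club transcripts. The sections of 1 specimen differed, with 3674 and 754.6 CPM in the epithelium-rich spots of specimen 2 and 339.9 and 5881 CPM in those of specimen 3, and with 12512 and 2501 CPM and 1343 and 15249 CPM in their club-high spots. Without specimens 4 and 5 edgeR called 4873 genes. The count was 3041 without specimen 2 and 508 without the specimen block (316 higher and 192 lower), and axes built from random genes of matched abundance gave 177 to 4622 called genes (median 1869).

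**Figure D3:**
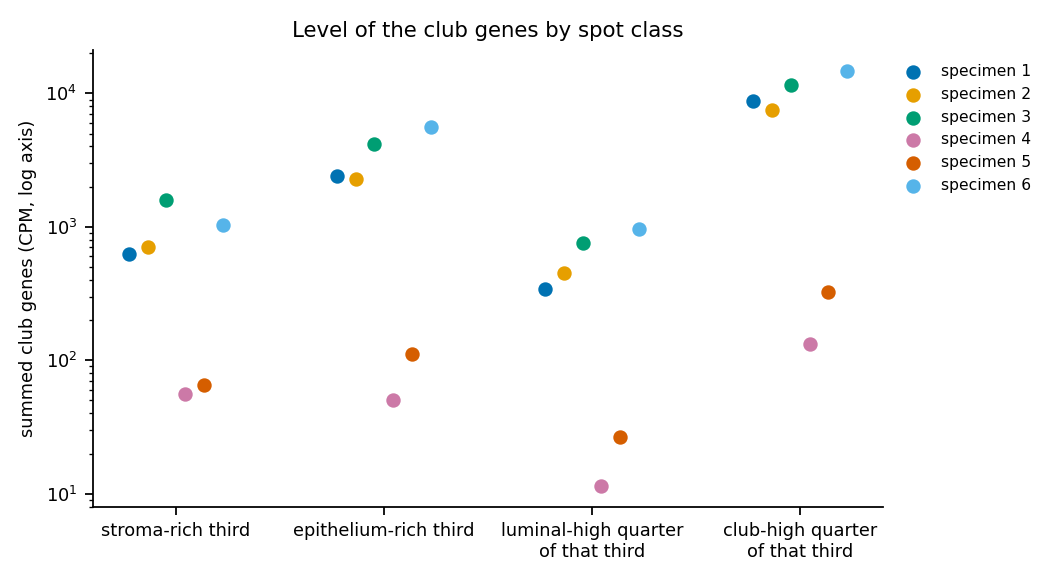
Summed CPM of the 6 club genes per specimen and spot class, on a log axis, with 1 point per specimen. Specimens 4 and 5 lie at 50 and 111.2 CPM in epithelium-rich spots and the other specimens between 2266 and 5597 CPM, of which specimens 2 and 3 each sum unlike sections (754.6 and 3674 CPM, 339.9 and 5881 CPM).

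Across single epithelium-rich spots, the club score was compared with the score of each gene list. For the androgen targets the mean partial Spearman rho was -0.299 ± 0.193 (SD, n = 6) and was negative in 6 of 6 specimens, with values of -0.412, -0.383, -0.373, -0.0012, -0.123 and -0.502 in specimens 1 to 6. An exact two-sided sign-flip permutation test over the 6 specimens gave p = 0.03125, the smallest that 6 specimens can give, and an adjusted p of 0.0717 over 39 lists, which did not pass. The other lists with a rho of 1 sign in 6 of 6 specimens included the luminal genes (-0.382 ± 0.2115), lipid synthesis (-0.163 ± 0.0997), antimicrobial genes (0.315 ± 0.184) and NF-kB (0.228 ± 0.1), each with the same exact permutation p and adjusted p. MHC class II had 0.244 ± 0.136 and was positive in 5 of 6 specimens (exact permutation p = 0.0625, adjusted p 0.102). With the luminal score held fixed as well, a step chosen after seeing the data, the mean rho moved to -0.0674 for androgen targets, -0.031 for lipid synthesis, 0.199 for antimicrobial genes, 0.132 for NF-kB and 0.1155 for MHC class II. Spots were thinned to 2000 UMIs, which kept 9252 of 9527 spots and left out 275, and without thinning the androgen target rho was -0.302, negative in 5 of 6 specimens, with p = 0.09375 in the same exact permutation test. Across specimens, the mean log2 CPM of the androgen targets in epithelium-rich spots was 7.59, 7.10, 6.71, 7.66, 7.57 and 6.54 in specimens 1 to 6. A planned test of its relation to the club level was left out after the club levels were seen. The club level summed per specimen fell into separate clusters of 2 and 4 specimens, too few for a correlation within either. Single sections, which are not independent, filled the gap with 339.9 and 754.6 CPM.

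**Figure D4:**
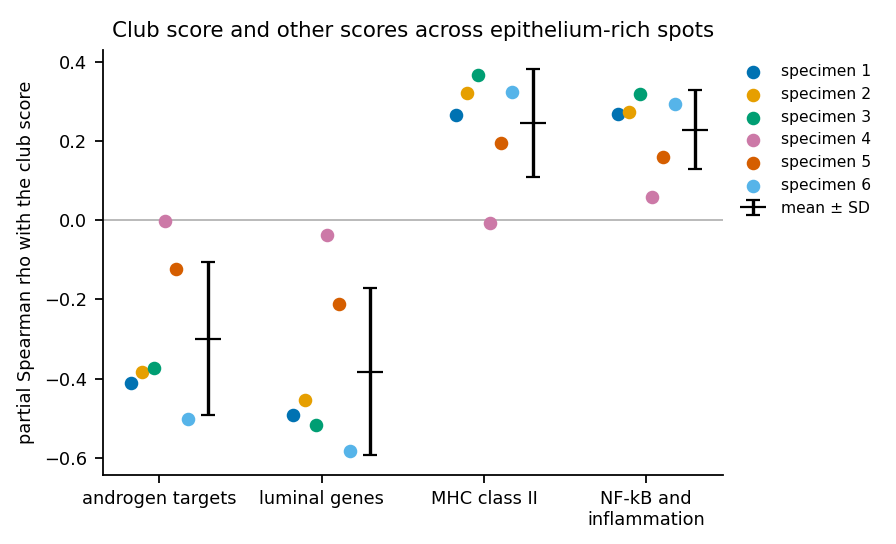
Partial Spearman rho between the club score and 4 other scores across epithelium-rich spots, with 1 point per specimen and the mean ± SD beside them. The androgen target values run from -0.502 in specimen 6 to -0.0012 in specimen 4, and the NF-kB values are positive in 6 of 6 specimens.

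Within the stroma-rich class, muscle-high and fibroblast-high spots differed in fewer genes and by smaller folds. In muscle-high spots CCN5, a secreted matricellular protein, was higher by a log2 fold change of 2.04 ± 0.24 (SE, n = 6) and CPXM2, a carboxypeptidase family member, by 1.85 ± 0.23. FHL1, a LIM protein of muscle, averaged 473.4 ± 270.6 against 188.2 ± 91.11 CPM (SD, n = 6). In fibroblast-high spots APOE, a lipid carrier, was higher, with a log2 fold change of -0.91 ± 0.11 for muscle-high against fibroblast-high, as was LTB (-0.86), a lymphotoxin of lymphocytes.

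Among genes with a mean of at least 20 CPM and the same direction in 6 of 6 specimens, the other largest increases were in SBSPON (1.53), SORBS2 (1.51), TNFRSF12A (1.41), HSPB7 (1.39), CCN3 (1.38), ITGA7 (1.27), an integrin of muscle, and FABP3 (1.26). Other large decreases among such genes were in CD48 (-0.79), RAB37 (-0.76), SLC38A5 (-0.73), FBLN2 (-0.73), GPC3 (-0.73), CCL19 (-0.72), a lymphoid chemokine, and PGF (-0.70). Each of these genes moved the same way in 6 of 6 specimens. edgeR called 500 genes higher and 293 lower of 11944 tested, of which 613 of 793 moved the same way in all 6 specimens, and CCN5 had an adjusted p of 3.96e-06 and APOE of 8.87e-06.

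Smooth muscle markers outside the axis rose in 8 of 11 cases (ACTA2 1.05, MYLK 0.74, SYNPO2 1.17). Fibroblast markers outside the axis were lower in muscle-high spots in 6 of 10 cases (IGF1 -0.63, CFD -0.70), and 2 of 14 oxidative phosphorylation genes were higher (COX6C 0.36, ATP5PF 0.30). The mitochondrial share of UMIs was higher in muscle-high spots in 7 of 8 sections, at 2.456% to 5.976% against 1.847% to 5.069%. Luminal secretory genes were lower in 6 of 6 cases (KLK3 -0.34, MSMB -0.30) and androgen targets in 6 of 26 (SPDEF -0.37, DHRS7 -0.26). MHC class II genes were lower in 9 of 10 (HLA-DQB1 -0.51), T and NK cell markers in 5 of 13 (CCL5 -0.38, CXCR4 -0.50), B and plasma cell markers in 2 of 9 (CD79B -0.65, MS4A1 -0.79) and macrophage markers in 0 of 11. The median of the B and plasma cell list was above 0 in specimens 2 and 6, at 0.03 and 0.86, and fry did not call that list (adjusted p 0.328), the macrophage markers (0.185), the androgen targets or the T and NK cell markers (0.0536 for both). Extracellular matrix genes parted, with 3 higher (COL4A2 0.79, CCN2 0.75, COL4A1 0.66) and 3 lower (MMP2 -0.61) of 22, as did growth factors, with 1 higher (SFRP4 0.78) and 6 lower (WNT2 -0.53) of 23. Adjusted over the list alone, 10 smooth muscle and 5 oxidative phosphorylation genes were higher, 6 fibroblast, 6 luminal, 10 androgen target, 9 MHC class II, 6 T and NK cell and 3 B and plasma cell genes were lower, 4 matrix genes went each way, and 3 growth factors were higher and 6 lower. camera called all of these lists except the matrix (adjusted p 0.304) and growth factors (0.154), with adjusted p from 2.36e-20 for smooth muscle to 0.0254 for macrophages. With an estimated correlation the adjusted p was 0.123 for smooth muscle, 0.226 for fibroblast, oxidative phosphorylation, luminal, androgen target, MHC class II and T and NK cell genes, 0.464 for B and plasma cell genes and 0.445 for macrophage genes. The count of called genes was 397 by DESeq2 (307 higher and 90 lower), 483 without specimen 3, 496 without specimens 4 and 5, 481 and 1214 with other definitions of axis or compartment, and 0 without the specimen block, where edgeR gave 459 genes an unadjusted p under 0.05.

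Leiden clustering of the spots gave 10 clusters, 9 of them made mostly of 1 section. With expression centred within sections, a step chosen after seeing the data, 10 clusters were again found, of which 4 were mostly of 1 section. A region led by ACTG2, CNN1, MYH11 and DES held 20.4% to 42.4% of the spots of each section, and a region led by GP2, RAB3B, SLC14A1 and KRT14 held 7.43% to 50.8%. A region led by JCHAIN, CCL19, LTB and CD52, genes of leukocytes, held 7.24% to 25.85%. A region led by MMP7, OLFM4, PIGR, SLPI, LCN2 and LTF held at least 1% of the spots in 7 of 8 sections, where it ran from 1.09% to 19.3%. A region led by NPY, RLN1, MSMB and KLK3 held 0.02% to 19.4%, with at least 1% in 4 of 8 sections. Luminal genes also led regions made mostly of 1 section. Such a region with AZGP1 and RLN1 held 35.5% of section 7. Another with MSMB, ACPP and NPY held 22.4% of section 1, and another with MSMB and NPY held 14.1% of section 3. The remaining region made mostly of 1 section was led by FAM83D, CPXM2, ALKAL1, MYOC and CCN5 and held 16.7% of section 1. Its leading genes also included HSPB7, and CCN5, CPXM2 and HSPB7 are among the genes named above as higher in muscle-high spots. A region led by HBA2, HBB, ACKR1 and AQP1, genes of red cells and vessels, held 2.83% to 10.5%.

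Positions on GRCh38 for key genes, from GENCODE 29 by Ensembl identifier, were as follows. MMP7 lies on chromosome 11 from 102520508 to 102530753, LTF on chromosome 3 from 46435645 to 46485234 and PIGR on chromosome 1 from 206928518 to 206946466. KLK3 lies on chromosome 19 from 50854915 to 50860764 and MSMB on chromosome 10 from 46033307 to 46046269. CXCL17 lies on chromosome 19 from 42428288 to 42443048, NPY on chromosome 7 from 24284163 to 24291865, ACTG2 on chromosome 2 from 73892314 to 73919865 and CCN5 on chromosome 20 from 44714844 to 44728509. All of these are annotated as protein-coding, and the counts are given per gene and not per transcript.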

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

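Each measure over the 6 specimens or 8 sections was searched for a highest or lowest value far from the others, and 28 of 382 groups held one. Chance flags about 1 in 20 groups. No test in this part was chosen after its result was seen, and no explanation was tested for these values.

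Section 6 had 173 spots under 500 UMIs, against 54 in the next section. In epithelium-rich spots, the 6 luminal genes summed to 104806 CPM in specimen 5, with 57911 CPM next, though the 2 sections of specimen 3 held 80368 and 26816 CPM. SCGB3A1 stood at 980.2 CPM in specimen 6 (next 233.6) and SCGB1A1 at 2317 CPM in specimen 6 (next 703.8).

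Among gene lists, the median log2 fold change of the unfolded protein response was 0.89 in specimen 5 for epithelium-rich against stroma-rich spots and -0.28 in specimen 4 for club-high against luminal-high spots. In the same club-high comparison, the progenitor-type list had 2.26 in specimen 6 and the growth factors had -0.27 in specimen 6, where fibroblast markers had -0.28 and smooth muscle markers -0.54.

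Among genes compared between club-high and luminal-high spots, specimen 4, where the club genes held 132.96 CPM in club-high spots, stood apart with log2 fold changes of 0.0928 for BCL2, 0.43 for GBP2 and 1.53 for TPSAB1. It also had 0 for CCL20, OLFM4 and PI3 and -0.67 for CP, but held 0 UMIs of the first 3 in both classes and 0 and 1 of CP, so these come from the prior count and measure no change. CHI3L2 had 4.74 in specimen 1, GSN had -0.17 in specimen 6, and the mast cell genes CPA3 and TPSB2 had 0.0129 and 0.0207 in specimen 6. Between epithelium-rich and stroma-rich spots, specimen 4 had -1.94 for NEXN, -0.59 for PGR and -1.44 for PIGR, the last on 6 and 7 UMIs, and specimen 1 had -3.16 for SCRG1. Between muscle-high and fibroblast-high spots, ACTA2 had 0.60 in specimen 5, and in specimen 1 CCN3 had 2.65 and IGHM -5.31, on 1 and 108 UMIs.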

How the results depend on the processing

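The tests without specimens 4 and 5, and with axes freed of leukocyte score or depth, were chosen after results were seen. All counts are edgeR calls unless named. Over 21 refitted alternatives the androgen target list kept a median log2 fold change of -1.59 to -1.06 and passed camera in each (largest adjusted p 1.21e-12). With an estimated correlation its value of -1.23 did not pass (limma adjusted p = 0.318). All 21 alternatives used the preset correlation and an axis that subtracts androgen-regulated luminal genes such as KLK3 or KLK2. They therefore cannot tell whether the fall of the list follows from the sorting. Of other list results in the club-high comparison 542 of 620 kept direction and side of the threshold, 393 of 418 for epithelium-rich and 196 of 231 for muscle-high spots, and for named genes 2627 of 2771, 1871 of 1889 and 1071 of 1234. These tallies pool unlike settings. With an estimated correlation 54 of the other list results lost the threshold and 6 kept their side. Without the specimen block 155 named genes lost the threshold and 139 kept their side.

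Without the replicate block, the counts were 4975, 508 and 0 for the epithelium-rich, club-high and muscle-high comparisons, the last with 459 genes at an unadjusted p under 0.05 in edgeR. The residual spread then includes differences between specimens. DESeq2, run with the block, gave 397 for muscle-high spots (307 higher, 90 lower, against 500 and 293). With each specimen left out the counts ran from 7236 to 8308, from 3041 (without specimen 2) to 4788 and from 483 (without specimen 3) to 801. For muscle-high spots, the count was 481 with the second part of each axis list (358 higher, 123 lower), 1214 with compartments of 50% and 496 without specimens 4 and 5. The cause was not tested for these. Reversed medians were -0.0525 for androgen metabolism in club-high spots with classes of 10%, -0.25 for B and plasma cells with the axis freed of the leukocyte score, where IGHG1 had -0.10, IGHM -0.17 and IGKC -0.19, and 0.0018 for growth factors in muscle-high spots with the second part of each axis list, and the cause was not tested.

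For the androgen target rho of -0.299, each specimen left out gave -0.359 to -0.259, and 8 sections as units gave -0.319, which passed (exact permutation p = 0.00781, adjusted 0.0190), though sections of 1 specimen are not independent. The relation across specimens was not computed, so its alternatives were not run. Low counts limit the club genes in specimens 4 and 5, with 545 and 1619 UMIs over epithelium-rich spots.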

Other observations

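In epithelium-rich against stroma-rich spots, hillock markers were higher in 7 of 10 cases and lower in 1 (AQP3 1.77, CLDN4 1.51), progenitor-type luminal genes in 9 of 12 (SOX9 1.60, PSCA 1.57) and luminal markers outside the axis in 13 of 14, with PCP4 lower at -2.30 (FOLH1 1.83, CD9 1.26). Mast cell markers were lower in 6 of 7 cases (CPA3, a mast cell protease, -1.63) and pericyte markers in 8 of 8 (ABCC9 -2.05, PDGFRB -1.33). The counts were the same adjusted over the list alone. limma's camera called all 5 lists, with adjusted p = 0.31 with an estimated correlation for all but the hillock genes, where it was 0.328. In club-high against luminal-high spots, hypoxia and glycolysis genes parted, with 4 higher and 3 lower of 12 (EGLN3 2.12, HK2 1.17, BNIP3 -1.04), or 5 and 3 adjusted over the list alone (camera adjusted p 0.265). Mast cell markers were higher in 3 of 6 cases (CPA3 0.48) and 4 adjusted over the list alone, and pericyte markers in 2 of 8 (NOTCH3 0.79) and 2 adjusted over the list alone, with camera adjusted p of 0.0341 and 0.0242 and 0.345 for both with an estimated correlation. Among 15 pairs of club genes across thinned epithelium-rich spots, PIGR and MMP7 had a mean rho of 0.24 ± 0.0234 (SD, n = 6), positive in 6 of 6 specimens (exact permutation p = 0.03125, adjusted 0.156), while SCGB1A1 had 0.0098 with MMP7 and 0.0169 with LTF. No pair passed the adjustment. Specimen 4 held only 6 UMIs of PIGR in its epithelium-rich spots before thinning, too few to measure a rho there. The shared sign in 6 of 6 specimens and the permutation p of PIGR and MMP7 rest on it in part.

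The test that held the luminal score fixed was chosen after the result was seen. The androgen target list was lower in club-high spots by camera, a call lost at adjusted p = 0.318 with an estimated correlation. With the axis freed of its linear trend with UMIs per spot the median was -1.12, which argues against such a trend as the whole cause. Only a linear trend was removed and that axis still subtracts luminal genes, so other effects of depth are not excluded. Of 20 axes of random genes, 0 gave a median as far from 0, but the club axis subtracts androgen-regulated luminal genes, so this decides nothing about the club genes. With the luminal score held fixed as well, the mean partial rho moved to -0.0674, so fewer luminal cells per spot may account for the relation. As luminal genes such as KLK3 and KLK2 are androgen-regulated, that test does not separate fewer luminal cells from a lower androgen response, and both stay open.

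The NF-kB list was higher in club-high spots by camera, a call lost at adjusted p = 0.318 with an estimated correlation. Its summed CPM was higher in 5 of 6 specimens, with a median log2 fold change of 0.07 in specimen 4, and T and NK cell markers summed to 320 ± 99.89 against 134.1 ± 53.37 CPM (SD, n = 6). With the axis freed of its linear trend with UMIs per spot, the median of the NF-kB list was 1.45. This argues against such a trend as the whole cause, and other effects of depth are not excluded. The median of the NF-kB list was 1.15 with the axis freed of its trend with the leukocyte score. That score held no neutrophil markers and only a linear trend was removed, so this value does not decide about leukocytes. A rise owed to leukocytes, in whole or in part, stays open. A part that follows from sorting on LCN2, LTF and PIGR also stays open and was not tested. The labels set no groups of sections, so no explanation by group was tested.

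Of 32 swaps of the classes within specimens, 1, the real one, gave as many genes in each of the 3 comparisons. The classes were sorted on an expression score in every section, which aligns them across specimens by construction, so these splits say nothing about chance. The real counts and the highest of the other swaps were 8605 and 1 for epithelium-rich, 4630 and 1948 for club-high and 793 and 2 for muscle-high spots. Of 20 random axes among epithelium-rich spots, 1 called 4622 genes and the next 2750 (median 1869), so none reached 4630 and 1 came close to it, and none were run for the other comparisons.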
